A study of Mus musculus with 8 samples.

How the data were processed

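Small-intestinal cells of mice given Fc or IL-22-Fc were measured by 10x Genomics 3' single-cell RNA sequencing in 8 libraries, 2 per treatment in each of an epithelial and a lamina propria fraction. Per the labels' protocols, epithelial cells came from EDTA fractions, of which the crypt-enriched last fraction was dissociated with TrypLE and passed through a 40-µm filter. Lamina propria cells came from the remaining tissue by enzyme digestion and a Percoll gradient, and dead cells were removed from both. Per the file headers, the deposited matrices hold raw UMI counts per gene and barcode made by the authors with Cell Ranger 7.1.0 on genome build mm10, with no normalization and without selection of barcodes as cells. The aligner settings are not given in the sources used here. Of 32285 gene identifiers, 32158 (99.61%) were found in GENCODE vM21, which gave the positions printed, on mm10.

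Cells were called separately in each fraction. Epithelial barcodes were kept with at least 1000 UMIs, 500 genes and at most 25% mitochondrial UMIs, and lamina propria barcodes with at least 500 UMIs, 300 genes and at most 10%. Doublets were scored with Scrublet as built into Scanpy at an expected 0.8% per 1000 cells. The automatic threshold was used unless it marked under 0.5% of cells, in which case the expected share with the highest scores was marked. That was the case for epithelial Fc replicates 1 and 2 and IL-22-Fc replicate 2 and for lamina propria IL-22-Fc replicate 1. Marked were 202, 931, 762 and 386 epithelial and 475, 807, 390 and 200 lamina propria cells (Fc 1, Fc 2, IL-22-Fc 1, IL-22-Fc 2). Cells left had median mitochondrial percents of 5.31, 6.12, 5.25 and 5.29 and of 2.68, 4.52, 3.51 and 4.13.

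Counts were scaled to 10000 per cell and log-transformed. The 2000 genes with the highest median rank of variability over the libraries were centred and scaled within each library. Then 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used in Scanpy 1.11.5 (AnnData 0.12.19, leidenalg 0.10.2, python-igraph 0.11.9, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0). Members of the IL-22/STAT3 response list, mitochondrial and ribosomal protein genes and variable segments of antibody and T cell receptor genes were left out of the clustering genes. Clusters were named from fixed marker lists when at least 3 markers were seen in 25% of their cells, the mean z-score was at least 0.5 and the 10 leading genes did not point to another class. Clusters that failed stayed unnamed. A cluster named as innate lymphocytes with at least 3 of Cd3d, Cd3e, Cd3g and Trac detected was called T-like, a rule added after the clusters were seen. Names end in "-like" because they rest on markers alone.

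UMIs were summed per class and library, so that libraries and not cells were the replicates. Classes with at least 20 cells in each library were tested. edgeR 4.0.16 (R 4.3.3, TMM scaling, filterByExpr, quasi-likelihood F test) compared IL-22-Fc with Fc at a Benjamini-Hochberg adjusted p of 0.05, with its default prior count for fold changes. CPM use TMM-scaled library sizes, except where receptor and ligand are described by class, with plain library sizes. Whether 2 classes responded differently was tested as an interaction with a term per library. The comparisons, their tests and most alternatives were set before the data were examined. A gene at 0 in a group was given a floor of 3 UMIs, and ratios on 1 to 3 UMIs carry a 95% counting interval.

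In all, 32 gene lists written before the data were examined were tested with limma 3.58.1 (camera with a preset correlation of 0.01, camera with an estimated correlation, and fry) where at least 5 members were tested. The list tests used log2 CPM with a prior count of 2. Class shares were compared by exact permutation of the libraries and by edgeR on cell counts. Genes named in the text were, per class, the 10 with the largest rise and the 10 with the largest fall among called genes with at least 20 CPM in the higher group and no overlap between groups. The 4 members with the smallest p of each list with at least 2 called members and a fixed set of genes were added. Some genes that this rule selects are not reported here. Genes of the difference between classes, of receptor and ligand, and leading genes of clusters are named besides. Mitochondrial, ribosomal protein and unnamed gene models were counted but not named.

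Alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, the replicate number as a block, each library left out in turn, doublets kept, the UMI minimum doubled, mitochondrial maxima of 15% and 5%, sums thinned to the smallest total, Leiden resolution 2, clustering without centring, and subtraction of free RNA. Free RNA was taken from barcodes with under 100 UMIs, up to the largest share that markers of absent classes allow. A library left alone in its group is assumed to vary like the other group. Alternatives chosen after seeing the data were the splits of the enterocyte-like class by cluster, the test of cluster 4, whole-library sums and a second profile of free RNA. That profile was taken from the barcodes ranked 20000 to 60000 by UMIs, which lie on the plateau of empty droplets in each library, with medians of 67 to 294 UMIs, where barcodes under 100 UMIs had a median of 1.

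The edgeR step was tested on simulated data with the real means and library sizes. It recovered 56.0% of genes changed 2-fold and 89.0% of genes changed 4-fold in the enterocyte-like comparison (11963 genes), 72.4% and 92.9% in stem/TA-like (13796), 72.4% and 94.9% in goblet-like (12177) and 38.1% and 92.9% in Paneth-like cells (11360). In the lamina propria it recovered 0% and 36.0% in T-like (10997 genes), 15.3% and 84.0% in plasma-like (12355) and 14.7% and 75.3% in macrophage/monocyte-like cells (7752), so counts of 0 there leave 2-fold changes, and in T-like cells 4-fold changes, possible. For the difference between enterocyte-like and stem/TA-like cells it recovered 84.5% of 4-fold differences (11904 genes). Unchanged genes called in error numbered 14 in enterocyte-like, 14 in stem/TA-like, 15 in goblet-like and 21 in Paneth-like cells. They numbered 4 in T-like, 19 in plasma-like and 7 in macrophage/monocyte-like cells, and 17 for the difference. Paneth-like cells had 37 and 91 genes recovered, and the difference 169. In each comparison false calls were a larger share of all calls than the adjusted p threshold sets. The same may hold for the calls reported here. Within a fraction no 2 libraries shared more than 0.3322% of barcodes. Dendritic-like cells were not tested because 1 library held 16. Figures were drawn with Matplotlib 3.10.9.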

Results

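Small-intestinal cells were profiled by droplet-based single-cell RNA sequencing in male C57BL/6 mice given IL-22-Fc, the cytokine interleukin-22 fused to an antibody Fc part, or Fc alone. The mice were 10 weeks old when a high-fat diet with 30% fructose in the drinking water began, and ate it for 16 weeks. In the last 4 of these weeks, 10 µg of protein was given into the peritoneal cavity at intervals of 3 days. Epithelial cells from a crypt-enriched preparation and leukocytes of the lamina propria, the connective tissue under the epithelium, were sequenced as separate fractions. Each fraction had 2 Fc and 2 IL-22-Fc libraries, 8 libraries in all. The labels number the libraries but do not say that each came from its own animal, so the p-values below measure only the spread between these libraries, which may be technical.

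The epithelial Fc libraries held 56239665 and 129938900 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule) and the epithelial IL-22-Fc libraries 140441685 and 103388724. After filters, 4820 and 9859 epithelial cells remained in the Fc libraries and 5844 and 6562 in the IL-22-Fc libraries, with medians of 7336, 8100, 14427 and 10446 UMIs per cell. The lamina propria Fc libraries held 123513064 and 57194253 UMIs and the IL-22-Fc libraries 110169803 and 67762569. They gave 8428 and 10966 Fc cells and 6592 and 6622 IL-22-Fc cells, with medians of 9227, 1607, 5576 and 5610 UMIs. Levels below are CPM, UMI counts of a class relative to its TMM-scaled library size, so they can differ from plain shares of UMIs. They are given as mean ± SD over the n = 2 libraries of a group, Fc first. Log2 changes are IL-22-Fc over Fc and carry their standard error. Every gene said to rise or fall passed an adjusted p of 0.05 in edgeR, and both its IL-22-Fc libraries lay on the same side of both Fc libraries.

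The series title names enterocyte STAT3, the transcription factor that IL-22 activates, so the first question was what IL-22-Fc changed in enterocyte-like cells, the absorptive cells of the villus. Reg3g (gene ENSMUSG00000030017, chromosome 6, 78466269 to 78468872), which encodes a secreted antimicrobial lectin, rose from 2241 ± 1223 to 49310 ± 4741 CPM (log2 change 4.46 ± 0.54, edgeR adjusted p = 0.0158). Its neighbour Reg3b (ENSMUSG00000071356, chromosome 6, 78370657 to 78373466) rose from 8555 ± 5635 to 133100 ± 13490 CPM (log2 change 3.96 ± 0.64, edgeR adjusted p = 0.0343). Reg3b and Reg3g together made up 1.20% of enterocyte-like UMIs in the Fc libraries and 16.5% in the IL-22-Fc libraries. The 2 genes are similar in sequence, so how reads split between them is uncertain. In all, edgeR called 431 of 12177 genes, 228 higher and 203 lower. The groups did not overlap for any of the 431, against 55.5% of all tested genes and 33.3% by chance. Clusters 7 and 8 held most enterocyte-like cells of the IL-22-Fc libraries, while the Fc libraries spread over clusters 7, 8, 10 and 15, of which cluster 10 is led by Apoa4 and Fabp1. Within clusters 10 and 15 alone, 185 genes passed. Without Fc replicate 1, Fc replicate 2, IL-22-Fc replicate 1 or IL-22-Fc replicate 2, the count was 1704, 3064, 128 or 200, and Reg3b no longer passed without IL-22-Fc replicate 1 (4.07) or 2 (3.86).

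Of 21 measured members of the IL-22/STAT3 response list, 10 rose in enterocyte-like cells and none fell (14 rose when adjusted over the list alone). The list's median log2 change was 2.67 (camera adjusted p = 1.9e-10), with an adjusted p = 0.642 with an estimated correlation. Fut2 (ENSMUSG00000055978, chromosome 7, 45648591 to 45666394), which adds fucose to the glycans of the epithelial surface, rose from 0.133 ± 0.188 to 29.9 ± 6.65 CPM (log2 change 7.32 ± 0.48, edgeR adjusted p = 0.0041). Dmbt1, a secreted protein that binds bacteria, rose from 256 ± 37.4 to 2513 ± 23.1 CPM (log2 change 3.30 ± 0.23, edgeR adjusted p = 0.00474). Duox2, an oxidase that makes hydrogen peroxide, rose from 9.60 ± 0.789 to 65.5 ± 10.7 CPM, and Tifa, an adaptor of innate immune signalling, from 21.9 ± 2.498 to 138 ± 17.7 CPM. Stat3 itself was at 54.2 ± 11.5 to 70.2 ± 3.41 CPM and Socs3, a feedback inhibitor of STAT3 signalling, at 17.8 ± 16.9 to 70.5 ± 12.3 CPM, and neither passed (edgeR adjusted p = 0.271 and 0.156). Il18, a cytokine of the epithelium, was at 213 ± 124 to 539.9 ± 61.4 CPM (edgeR adjusted p = 0.137). Leaving out a library moved these into the calls: Stat3 passed without Fc replicate 1 (log2 change 0.60), and Socs3 and Il18 without Fc replicate 1 (1.24 and 2.10) or Fc replicate 2 (3.59 and 0.85).

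Genes outside that list were called in enterocyte-like cells as well. Rhoj (ENSMUSG00000046768, chromosome 12, 75308322 to 75401456), a small GTPase, was at 0 UMIs in both Fc libraries and 25.1 ± 3.31 CPM in the IL-22-Fc libraries, at least 186-fold higher against a floor of 3 UMIs over the group. B3galt5 (ENSMUSG00000074892, chromosome 16, 96235801 to 96319859), a galactosyltransferase of glycan chains, had 3 UMIs in the Fc libraries and 3358 in the IL-22-Fc libraries, a ratio of 792 with a 95% counting interval of 271 to 3841. Lrg1 (ENSMUSG00000037095, chromosome 17, 56119678 to 56122001), a secreted leucine-rich glycoprotein, rose from 0.617 ± 0.308 to 92.2 ± 2.49 CPM (log2 change 7.37 ± 0.26, edgeR adjusted p = 0.000966). Chst4, a sulfotransferase of glycans, rose from 2.35 ± 0.221 to 55.6 ± 4.69 CPM, and Gcnt3, which branches mucin-type glycans, from 2.18 ± 1.71 to 37.1 ± 11.1 CPM. Gpx2, a glutathione peroxidase of the gut, rose from 560.2 ± 48.4 to 2260 ± 234 CPM (2.01 ± 0.21). The list of Paneth cell peptides was higher in these enterocyte-like cells (median 0.78, camera adjusted p = 2.02e-06, and adjusted p = 0.642 with an estimated correlation), with 2 of 16 members passing, Mptx2 (24.2 to 90.7 CPM) and Mmp7 (10.9 to 26.04 CPM), and 11 when adjusted over the list alone. Markers of Paneth-like cells, Mmp7 among them, were taken as absent here to set the upper share of free RNA, 4.165% to 5.843% of UMIs. Free RNA could therefore carry these markers as a whole, and whether enterocyte-like cells made them was not tested. Asns, which makes asparagine, rose from 14.03 ± 0.222 to 54.4 ± 2.097 CPM. Gcnt3 and Gpx2 no longer passed without IL-22-Fc replicate 2 (log2 change 3.61 and 1.91), nor Mmp7 without IL-22-Fc replicate 1 or 2 (1.22 and 1.28) or after free RNA was subtracted (3.80).

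Lists of metabolic genes were tested in enterocyte-like cells. The list of PPARα targets and fatty acid oxidation had a median log2 change of -0.68 (mean -1.21, camera adjusted p = 1.83e-06, and adjusted p = 0.642 with an estimated correlation), with 5 of 25 members falling and 13 when adjusted over the list alone, where 1 rose. Ppara, the nuclear receptor that drives these genes, fell from 159 ± 17.7 to 76.5 ± 7.596 CPM (log2 change -1.06 ± 0.15, edgeR adjusted p = 0.0235). Acaa1b, a peroxisomal thiolase, fell from 94.3 ± 48.2 to 6.15 ± 1.72 CPM, and Angptl4, an inhibitor of lipoprotein lipase, from 28.1 ± 12.8 to 2.06 ± 1.096 CPM. In the fat absorption list, 4 of 29 members fell (12 when adjusted over the list alone, median -0.95, camera adjusted p = 1.33e-07, and adjusted p = 0.642 with an estimated correlation). Cd36 (ENSMUSG00000002944, chromosome 5, 17781690 to 17888801), a fatty acid transporter, fell from 44.5 ± 8.43 to 15.7 ± 3.07 CPM (log2 change -1.50 ± 0.21, edgeR adjusted p = 0.022). The abundant lipid carriers Fabp1 (16620 ± 5971 to 7621 ± 3040 CPM) and Apoa4 (2866 ± 282 to 895 ± 644 CPM), which also lead cluster 10, did not pass (edgeR adjusted p = 0.213 and 0.146). Ppara and Acaa1b no longer passed without IL-22-Fc replicate 1 (-1.15 and -3.66) or 2 (-0.95 and -4.24), nor Cd36 and Angptl4 without IL-22-Fc replicate 1 (-1.30 and -3.28). Fabp1 passed without Fc replicate 2 (-1.45) and Apoa4 without IL-22-Fc replicate 2 (-2.70).

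In the list of sugar handling 3 of 18 members fell (13 lower and 1 higher when adjusted over the list alone), with a median of -0.96 (camera adjusted p = 3.61e-05, and adjusted p = 0.642 with an estimated correlation). Fbp1, an enzyme of gluconeogenesis, fell from 130.4 ± 24.9 to 29.9 ± 9.71 CPM, and Slc5a4b, of the sodium-glucose transporter family, from 64.8 ± 27.1 to 8.75 ± 3.21 CPM. Pck1 (ENSMUSG00000027513, chromosome 2, 173153048 to 173159273), which catalyses the first committed step of gluconeogenesis, fell from 41.03 ± 2.17 to 1.46 ± 0.789 CPM (log2 change -4.80 ± 0.32, edgeR adjusted p = 0.0041). The glucose transporter Slc5a1 (679.5 ± 186 to 505 ± 192 CPM) and the fructose transporter Slc2a5 (191 ± 144 to 138 ± 90.7 CPM) overlapped between groups (edgeR adjusted p = 0.49 and 0.714). Khk, which phosphorylates fructose, was at 605 ± 103 to 362 ± 72.4 CPM (edgeR adjusted p = 0.137). Cyp3a11 (ENSMUSG00000056035, chromosome 5, 145854426 to 145879964), a cytochrome P450 that oxidises drugs and steroids, fell from 53.3 ± 19.9 to 1.05 ± 0.4803 CPM (log2 change -5.67 ± 0.41, edgeR adjusted p = 0.00522). Its near-identical relatives share reads, so its level is uncertain. Rdh7, a retinol dehydrogenase, fell from 213 ± 18.96 to 23.7 ± 2.602 CPM, Scd1, the stearoyl-CoA desaturase, from 8.01 ± 3.82 to 0.286 ± 0.0488 CPM, and Nr0b2, a nuclear receptor induced by bile acids, from 7.42 ± 3.08 to 0.318 ± 0.00429 CPM. Fbp1 no longer passed without Fc replicate 1 (-2.31) or 2 (-1.92), nor Slc5a4b without IL-22-Fc replicate 1 (-2.55). Khk passed without Fc replicate 2 (-0.91), and without it or without IL-22-Fc replicate 1 the change of Slc2a5 was positive (0.63 and 0.08).

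**Figure D1:**
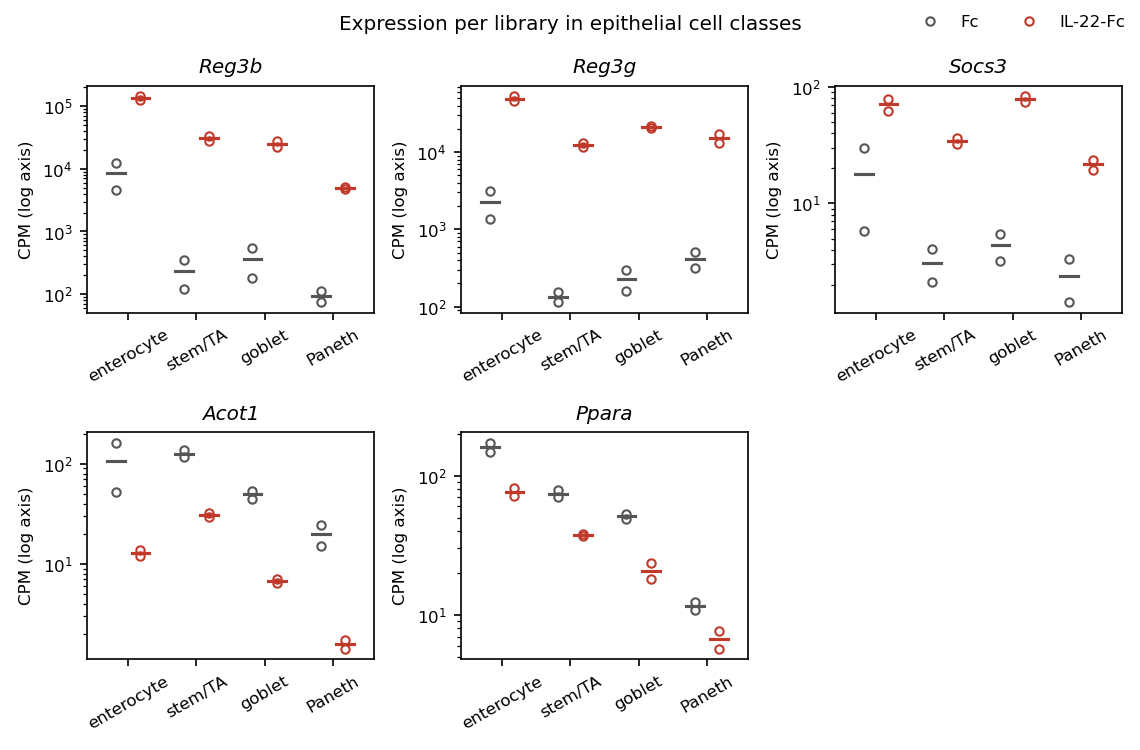
CPM on a log axis of 5 genes in 4 epithelial cell classes; open circles are libraries (grey Fc, red IL-22-Fc, 2 per group) and bars are group means. Reg3b, Reg3g and Socs3 lie higher and Acot1 and Ppara lower in both IL-22-Fc libraries of every class drawn, although Socs3 in enterocyte-like cells did not pass the test.

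The same comparison in stem/TA-like cells (stem cells and their dividing, transit-amplifying offspring) also held calls in the IL-22/STAT3 list. Reg3b rose from 234 ± 157 to 30740 ± 3645 CPM (log2 change 7.04 ± 0.63, edgeR adjusted p = 0.00103) and Reg3g from 134 ± 29.2 to 12220 ± 1077 CPM (log2 change 6.51 ± 0.35, edgeR adjusted p = 5.19e-05). Rhoj rose from 0.0797 ± 0.0435 to 73.8 ± 5.67 CPM (log2 change 9.99 ± 0.23, edgeR adjusted p = 7.07e-07) and Lrg1 from 0.175 ± 0.143 to 33.1 ± 2.83 CPM. Of 22 IL-22/STAT3 list members, 15 rose and none fell (18 when adjusted over the list alone, median 2.18, camera adjusted p = 5.4e-15, and adjusted p = 0.421 with an estimated correlation). Socs3 (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047) rose from 3.11 ± 1.39 to 34.3 ± 2.95 CPM (log2 change 3.55 ± 0.28, edgeR adjusted p = 0.00185) and Stat3 from 19.2 ± 2.04 to 49.3 ± 1.55 CPM (log2 change 1.37 ± 0.12, edgeR adjusted p = 0.000471). Duoxa2, the partner protein of Duox2, rose from 3.15 ± 0.7002 to 33.3 ± 6.199 CPM, Duox2 from 7.63 ± 0.145 to 37.95 ± 0.0103 CPM, and Lcn2, which withholds iron from bacteria, from 0.224 ± 0.0743 to 9.05 ± 1.91 CPM. Sulf2 (ENSMUSG00000006800, chromosome 2, 166073089 to 166155663), which removes sulfate from heparan sulfate chains, rose from 2.16 ± 0.223 to 26.7 ± 0.894 CPM, and Cfi, a regulator of complement, from 4.09 ± 0.537 to 33.1 ± 1.83 CPM. Of 14001 genes, edgeR called 1248, 633 higher and 615 lower. The groups did not overlap for any of the 1248, against 59.5% of all tested genes and 33.3% by chance. Without Fc replicate 1, Fc replicate 2 or IL-22-Fc replicate 2 the count was 3890, 5792 or 608.

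In stem/TA-like cells the calls in 2 lists of lipid genes went in opposite directions. Of 21 cholesterol synthesis genes, 11 rose and none fell (17 when adjusted over the list alone, median 0.63, camera adjusted p = 1.29e-09, and adjusted p = 0.553 with an estimated correlation). Fdps and Sqle, enzymes of the pathway, rose from 59.8 ± 9.29 to 149.6 ± 13.9 CPM and 19.5 ± 3.51 to 42.3 ± 3.698 CPM. Of 25 PPARα target genes, 14 fell and 1 rose (15 and 1 when adjusted over the list alone, median -0.55, camera adjusted p = 6.06e-09, and adjusted p = 0.553 with an estimated correlation). Acot1 (ENSMUSG00000072949, chromosome 12, 84009490 to 84018371), an acyl-CoA thioesterase, fell from 127 ± 15.6 to 30.7 ± 1.84 CPM (log2 change -2.04 ± 0.13, edgeR adjusted p = 9.41e-05), and Ppara from 74.03 ± 6.04 to 37.5 ± 0.835 CPM. Acot1 has close copies that can share its reads. Ces1d, a carboxylesterase, fell from 20.6 ± 3.76 to 1.75 ± 0.523 CPM and Ttr (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321), a carrier of thyroid hormone and retinol, from 39.8 ± 4.08 to 7.76 ± 0.0423 CPM. Abcb1a, an efflux transporter, fell from 53.5 ± 3.15 to 12.3 ± 1.57 CPM, and Slit2 (ENSMUSG00000031558, chromosome 5, 47983138 to 48307733), a secreted guidance protein, from 70.2 ± 7.75 to 17.7 ± 0.864 CPM.

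Lists of antigen presentation, division and stem cell genes were also tested in stem/TA-like cells. Of 7 MHC class II genes, 6 rose (7 when adjusted over the list alone, median 1.26, camera adjusted p = 3.32e-07, and adjusted p = 0.421 with an estimated correlation). H2-Aa rose from 36.99 ± 4.86 to 106 ± 2.35 CPM (log2 change 1.53 ± 0.12, edgeR adjusted p = 0.000307) and H2-Ab1 from 79.5 ± 8.15 to 192 ± 10.5 CPM (log2 change 1.27 ± 0.12, edgeR adjusted p = 0.000732). Their sequences are similar to those of other class II genes, so some reads may be shared. Of 15 interferon-stimulated genes, 5 rose and 1 fell (9 and 1 when adjusted over the list alone, median 0.53, camera adjusted p = 0.000107, and adjusted p = 0.421 with an estimated correlation), among them Psmb8, an immunoproteasome subunit (104 to 200.4 CPM). Of 31 cell cycle genes, 8 rose (16 when adjusted over the list alone, median 0.35, camera adjusted p = 5.69e-05, and adjusted p = 0.421 with an estimated correlation), such as Ccnd1 (187 ± 19.5 to 309 ± 13.7 CPM), which encodes cyclin D1. The cell cycle and stem cell lists share members with the markers that define the class, such as Mki67, Top2a, Lgr5 and Olfm4. Cluster 0 of the class held 12.1% and 17.6% of Fc cells and 9.58% and 8.15% of IL-22-Fc cells. The shares of clusters 1, 2 and 3 overlapped between groups. Whether the mix of clusters plays a part was not tested. Of 16 stem cell genes, 10 fell (14 lower and 1 higher when adjusted over the list alone, median -0.57, camera adjusted p = 2.86e-06, and adjusted p = 0.553 with an estimated correlation). Among them Rgmb fell from 164 ± 16.0 to 93.0 ± 11.1 CPM and Axin2, a Wnt target gene, from 123 ± 12.7 to 79.4 ± 4.26 CPM, and neither passed without IL-22-Fc replicate 2 (log2 change -0.69 and -0.57). Lgr5 (236 ± 16.1 to 137 ± 25.5 CPM), Olfm4 (3469 ± 3.46 to 2056 ± 45.9 CPM) and Mki67 (365 ± 58.8 to 328 ± 15.1 CPM) are markers that define the class and are given as values only (log2 change of Lgr5 -0.60 without IL-22-Fc replicate 2, of Olfm4 -0.76 and -0.75 and of Mki67 0.02 and -0.30 without Fc replicate 1 and 2).

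**Figure D2:**
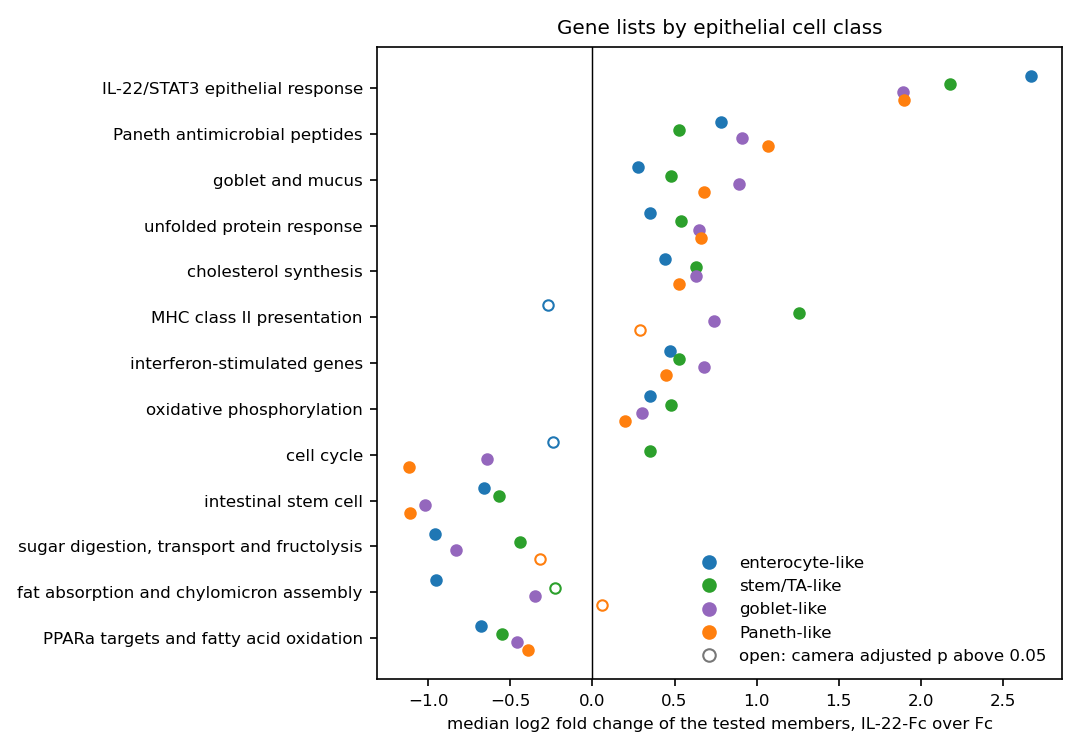
Median log2 fold change of 13 gene lists (IL-22-Fc over Fc) in 4 epithelial cell classes; filled circles have a camera adjusted p below 0.05 with a preset correlation of 0.01 and open circles do not. The IL-22/STAT3 list lies highest in each class, between 1.89 and 2.67, and the PPARα list lies below 0 in each, between -0.68 and -0.39. With an estimated correlation no list passed in any class.

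In goblet-like cells, which secrete mucus, Retnlb showed the largest rise. Retnlb (ENSMUSG00000022650, chromosome 16, 48816856 to 48818892), which encodes the antimicrobial protein RELMβ, rose from 0.899 ± 0.0672 to 1005 ± 61.2 CPM (log2 change 10.12 ± 0.25, edgeR adjusted p = 1.26e-05). Fut2 rose from 1.68 ± 1.48 to 202 ± 2.24 CPM (log2 change 6.70 ± 0.34, edgeR adjusted p = 0.000247), Socs3 from 4.38 ± 1.62 to 78.4 ± 6.14 CPM (log2 change 4.24 ± 0.23, edgeR adjusted p = 0.000294) and Lrg1 from 0.207 ± 0.0691 to 60.4 ± 4.95 CPM. Reg3g rose from 228 ± 96.4 to 21100 ± 1237 CPM and Reg3b from 366 ± 259 to 24830 ± 4077 CPM. Tac1, the precursor of substance P, rose from 2.74 ± 0.141 to 113 ± 23.7 CPM, and Nupr1, a stress-induced chromatin protein, from 51.6 ± 19.9 to 336 ± 18.98 CPM. Mmp7, the protease that activates α-defensins, rose from 189 ± 8.44 to 995 ± 10.4 CPM. It is among the Paneth-like markers that set the upper share of free RNA in goblet-like cells. The subtraction thus takes these markers as a whole to be free RNA. Of 20 IL-22/STAT3 list members, 15 rose (15 when adjusted over the list alone, median 1.89, camera adjusted p = 4.7e-11, and adjusted p = 0.535 with an estimated correlation). Of 12363 genes, edgeR called 1139, 655 higher and 484 lower. The groups did not overlap for any of the 1139, against 62.8% of all tested genes and 33.3% by chance. Cluster 5, led by Dll1 and Creb3l1, held 6.60% and 4.72% of Fc cells and 2.19% and 3.34% of IL-22-Fc cells, and cluster 6, led by Zg16 and Fcgbp, 3.36% and 5.55% against 7.70% and 6.78%. Without Fc replicate 1, Fc replicate 2, IL-22-Fc replicate 1 or IL-22-Fc replicate 2, the count was 2928, 5350, 118 or 280.

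Lists of secretion, lipid and division genes were tested in goblet-like cells. The mix of goblet-like clusters given above differed between groups. Whether it plays a part in the goblet-like calls and lists was not tested. Of 20 genes of the unfolded protein response, 10 rose (17 when adjusted over the list alone, median 0.65, camera adjusted p = 1.03e-08, and adjusted p = 0.452 with an estimated correlation), including Asns (55.8 ± 0.991 to 152 ± 3.89 CPM) and Chac1, a glutathione-degrading enzyme (0.4496 ± 0.0336 to 5.403 ± 0.905 CPM). Of 19 goblet and mucus genes, 6 rose (17 when adjusted over the list alone, median 0.89, camera adjusted p = 5.1e-07, and adjusted p = 0.535 with an estimated correlation). Every marker that defines the class, such as Muc2, Tff3 and Zg16, is a member of this list, so it is no independent view of these cells. C1galt1, which builds the core of mucin glycans, rose from 144 ± 32.3 to 293 ± 8.83 CPM, but no longer passed without IL-22-Fc replicate 1 (0.99) or 2 (1.05). Of 21 cholesterol synthesis genes, 10 rose (19 when adjusted over the list alone, median 0.63, camera adjusted p = 1.48e-08, and adjusted p = 0.535 with an estimated correlation). Of 31 cell cycle genes, 13 fell (27 when adjusted over the list alone, median -0.64, camera adjusted p = 4.31e-09, and adjusted p = 0.535 with an estimated correlation), where 8 of 31 rose in stem/TA-like cells. That difference between classes was not tested. Mki67, a marker of dividing cells, fell from 277 ± 82.5 to 142 ± 1.04 CPM, and passed neither without IL-22-Fc replicate 1 (-0.94) nor 2 (-0.96). Of 24 PPARα target genes, 8 fell and 1 rose (13 and 1 when adjusted over the list alone, median -0.46, camera adjusted p = 6.38e-06, and adjusted p = 0.535 with an estimated correlation), with Acot1 at 49.4 ± 6.71 to 6.74 ± 0.434 CPM. Reg4, a secreted lectin, fell from 129.8 ± 0.767 to 21.8 ± 2.59 CPM.

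In Paneth-like cells, the antimicrobial cells of the crypt base, Wfdc18 (ENSMUSG00000000983, chromosome 11, 83709015 to 83711348), a secreted protease inhibitor-like protein, rose from 0.727 ± 0.0606 to 66.98 ± 29.7 CPM (log2 change 6.52 ± 0.41, edgeR adjusted p = 0.00247). Retnlb rose from 4.47 ± 0.301 to 283 ± 17.9 CPM (log2 change 5.98 ± 0.24, edgeR adjusted p = 0.000241), and complement C4b from 1.97 ± 0.479 to 42.1 ± 4.15 CPM. Reg3g rose from 412 ± 128 to 15200 ± 2778 CPM, Cfi from 7.08 ± 1.46 to 53.5 ± 3.25 CPM and Lgmn, a lysosomal protease, from 34.5 ± 13.5 to 227 ± 22.2 CPM. Reg3b was at 93.6 ± 27.2 to 4954 ± 257 CPM, a level that free RNA in the droplets could supply in full. Of 17 IL-22/STAT3 list members, 10 rose (14 when adjusted over the list alone, median 1.90, camera adjusted p = 6.47e-16, and adjusted p = 0.523 with an estimated correlation). Acot1 fell from 19.9 ± 6.71 to 1.57 ± 0.214 CPM, Ccnd2, which encodes cyclin D2, from 47.2 ± 13.9 to 7.44 ± 0.343 CPM, and Vdr, the vitamin D receptor, from 40.97 ± 9.46 to 10.9 ± 2.53 CPM. Of 11584 genes, edgeR called 89, 59 higher and 30 lower. The groups did not overlap for any of the 89, against 57.2% of all tested genes and 33.3% by chance. None of 31 cell cycle genes passed, while 23 were lower when adjusted over the list alone (median -1.12, camera adjusted p = 1.2e-08, and adjusted p = 0.573 with an estimated correlation). Clusters 9 and 12, led by Pnliprp2 and Reg4, held most Paneth-like cells of the Fc libraries. Cluster 14, led by Mptx2 and Defa34, held most of those in the IL-22-Fc libraries. Whether this mix plays a part in the Paneth-like calls and lists was not tested. After subtraction of free RNA edgeR called 0 genes, and without Fc replicate 1 or Fc replicate 2 it called 1420 or 5252. Without either of these, Wfdc18 did not pass (log2 change 6.44 and 6.63).

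Rarer epithelial classes were compared as well. In tuft-like cells, chemosensory cells of the epithelium, edgeR called 131 of 9255 genes, 35 higher and 96 lower, all without overlap between groups (45.6% of all tested genes, 33.3% by chance). Socs3 rose from 3.42 ± 2.36 to 36.2 ± 6.305 CPM (log2 change 3.49 ± 0.47, edgeR adjusted p = 0.00503) and Nfasc, a cell adhesion protein, from 5.03 ± 1.12 to 59.4 ± 19.2 CPM. Chgb (ENSMUSG00000027350, chromosome 2, 132781278 to 132795079), a granule protein of endocrine cells, fell from 267 ± 35.7 to 2.704 ± 0.494 CPM (log2 change -6.56 ± 0.33, edgeR adjusted p = 6.96e-07), and Egfr, the receptor of epidermal growth factor, from 53.7 ± 19.99 to 7.36 ± 5.42 CPM. Of 30 cell cycle genes, 7 fell (26 when adjusted over the list alone, median -1.40, camera adjusted p = 6.3e-18, and adjusted p = 0.724 with an estimated correlation). With doublets kept, Chgb did not pass (log2 change -1.63). The tuft-like count was 563 without Fc replicate 2, 49 without IL-22-Fc replicate 1 and 285 without IL-22-Fc replicate 2. In enteroendocrine-like cells, which make gut hormones, edgeR called 2 of 10391 genes, among them Afp, which helps to define cluster 22 of this class. With the replicate number as a block it called 0, and with doublets kept 90. The count was 4, 19, 100 and 630 without Fc replicate 1, Fc replicate 2, IL-22-Fc replicate 1 and IL-22-Fc replicate 2. In T-like cells of this fraction 8 genes rose and 1 fell of 6476 tested, all without overlap between groups (29.9% of all tested genes, 33.3% by chance). Those named that rose, Reg3g (78.3 ± 20.7 to 3685 ± 755 CPM), Reg3b (235 ± 62.01 to 7935 ± 1923 CPM), Mptx2, Mmp7, Agr2 and Dmbt1, are products of epithelial cells, and Nr4a2, an immediate early gene, fell from 229.8 ± 116 to 52.3 ± 24.8 CPM. After subtraction of free RNA 2 other genes were called and none of these 9, with Nr4a2 at -1.91, and DESeq2 called 6, all higher. The T-like count was 43, 238 and 14 without Fc replicate 1, Fc replicate 2 and IL-22-Fc replicate 1, and Nr4a2 did not pass without IL-22-Fc replicate 1 (-1.64), nor Mmp7 (1.99) and Dmbt1 (1.61) without IL-22-Fc replicate 2.

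Cluster 4 was left unnamed by the naming rule and was tested by its number, a choice made after the clusters were seen. Its leading genes are Rbp7, Lrg1 and Gsdmc4, and it held 99 and 619 Fc cells and 405 and 624 IL-22-Fc cells. Reg3b rose from 689 ± 403 to 98590 ± 12730 CPM (log2 change 7.17 ± 0.59, edgeR adjusted p = 3.26e-07), Reg3g from 372 ± 42.8 to 35050 ± 3843 CPM, and Socs3 from 3.75 ± 0.914 to 69.9 ± 6.47 CPM (log2 change 4.38 ± 0.27, edgeR adjusted p = 8.11e-09). B3galt5 and Rhoj were at 0 UMIs in both Fc libraries and at least 160.1-fold and 111-fold higher in the IL-22-Fc libraries. Hsd3b3, a steroid dehydrogenase, fell from 34.05 ± 4.74 to 1.77 ± 0.2896 CPM, Mme, a membrane peptidase, from 28.1 ± 0.718 to 1.75 ± 0.8203 CPM, and Acot1 from 104 ± 9.71 to 24.1 ± 0.523 CPM. Of 18 IL-22/STAT3 list members, 16 rose (16 when adjusted over the list alone, median 2.84, camera adjusted p = 2.81e-19, and adjusted p = 0.465 with an estimated correlation). Of 10898 genes, edgeR called 1011, 586 higher and 425 lower, and the groups did not overlap for 1010 of them (55.6% of all tested genes, 33.3% by chance). Without Fc replicate 1, Fc replicate 2, IL-22-Fc replicate 1 or IL-22-Fc replicate 2, the count was 1619, 2033, 554 or 341.

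Whether enterocyte-like and stem/TA-like cells responded differently was tested directly, in a fit with both classes of each library. Of 13789 genes, edgeR called 95, with 39 responses higher and 56 lower in enterocyte-like cells. Fewer genes were called after subtraction of free RNA by the first profile, as given below. The enterocyte-like clusters were mixed differently in the Fc and IL-22-Fc libraries, as given above. The difference was not tested within clusters, so a shift in that mix cannot be told apart from a different response. Sulf2 went from 44.2 to 53.4 CPM in enterocyte-like and 2.16 to 26.7 CPM in stem/TA-like cells (difference of log2 changes -3.37 ± 0.18, edgeR adjusted p = 0.00155). Reg3b rose less in enterocyte-like cells, which started higher (difference -3.12 ± 0.20, edgeR adjusted p = 0.00291), and so did Reg3g (-1.99 ± 0.25). Among MHC class II genes, H2-Ab1 went from 258 to 164 CPM in enterocyte-like and 79.5 to 192 CPM in stem/TA-like cells (difference -1.97 ± 0.20, edgeR adjusted p = 0.0178), and Cd74, the class II invariant chain, from 800.1 to 712 CPM in enterocyte-like and 358 to 856 CPM in stem/TA-like cells (-1.46 ± 0.18). Tm4sf4 (ENSMUSG00000027801, chromosome 3, 57425314 to 57441677), a membrane protein of the tetraspanin-like family, fell more in enterocyte-like cells (difference -2.27 ± 0.16), as did Fbp1 (-1.64 ± 0.18) and Slc5a4b (-2.76 ± 0.35). Oxct1, the enzyme that lets cells use ketone bodies, went from 43.2 to 154 CPM in enterocyte-like and 104 to 125 CPM in stem/TA-like cells (difference 1.52 ± 0.12, edgeR adjusted p = 0.00586). Gcnt3 also rose more in enterocyte-like cells (3.30 ± 0.38), as did the antiviral cytidine deaminase Apobec3, which went from 4.82 to 28.6 CPM in enterocyte-like and 53.4 to 98.8 CPM in stem/TA-like cells. Without IL-22-Fc replicate 1 edgeR called 0 genes, with 693 at an unadjusted p under 0.05, and without IL-22-Fc replicate 2 it called 3. The differences without IL-22-Fc replicate 1, none of them past the threshold, were Sulf2 -3.14, Reg3b -3.06, Reg3g -1.9, H2-Ab1 -1.67, Cd74 -1.24, Tm4sf4 -2.17, Fbp1 -1.3, Slc5a4b -2.43, Oxct1 1.71, Gcnt3 3.58 and Apobec3 1.67. Those without IL-22-Fc replicate 2, where of the genes named only Sulf2 passed, were Reg3b -3.02, Reg3g -1.91, H2-Ab1 -2.1, Cd74 -1.52, Tm4sf4 -2.2, Fbp1 -1.82, Slc5a4b -2.9, Oxct1 1.5, Gcnt3 3.32 and Apobec3 1.72. Without Fc replicate 1 or Fc replicate 2 it called 535 or 1209.

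**Figure D3:**
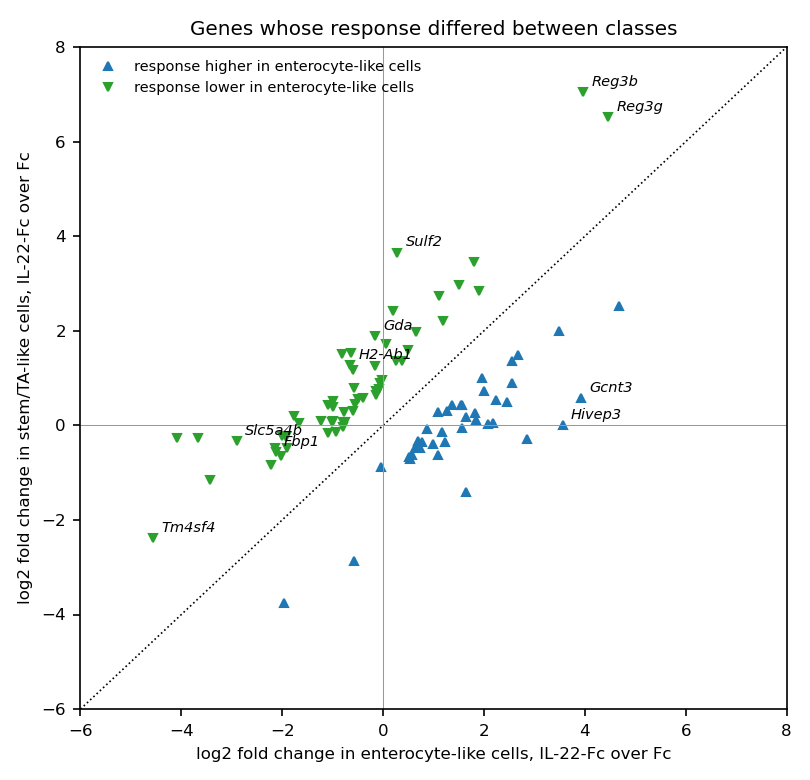
Log2 fold change (IL-22-Fc over Fc) in enterocyte-like cells on the horizontal axis and stem/TA-like cells on the vertical axis, 1 triangle per gene with a response that differed; the dotted line marks equal responses. The 56 downward triangles lie above the line and the 39 upward triangles below it, with Reg3b and Reg3g at the top right.

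Which cells carry the receptor of the injected protein was described without a test. Transcripts of Il22ra1 (ENSMUSG00000037157, chromosome 4, 135728172 to 135752140), the receptor chain specific to the IL-22 family, were at 10.2 ± 3.03 CPM in enterocyte-like cells of the Fc libraries and 4.93 ± 0.44 in the IL-22-Fc libraries, before composition scaling, a difference that edgeR did not call (adjusted p = 0.17). Goblet-like cells had 5.30 ± 0.639 and 5.76 ± 0.976 CPM, Paneth-like cells 3.18 ± 1.62 and 1.56 ± 0.217, and stem/TA-like cells 2.93 ± 0.52 and 1.78 ± 0.397. A UMI of Il22ra1 was seen in 8.15% ± 1.30 and 6.94% ± 2.05 of enterocyte-like cells, whose library medians ran from 7080 to 16730 UMIs, against 0.442% ± 0.626 of T-like Fc cells (1 UMI in 391 cells, at medians of 1176 and 1390 UMIs) and 0% of T-like IL-22-Fc cells (0 UMIs in 594 cells), which should lack it. Thinned to 1000 UMIs per cell, the shares were 1.34% and 0.308% of enterocyte-like cells and 0.442% and 0% of T-like cells. The upper 95% limit on 0 of 594 cells is 0.6191%, so these T-like cells are too few to place the 0.308% above or below background. In the lamina propria, ILC3-like cells (innate lymphocytes that make IL-22) had 750 ± 359 CPM of Il22 in the Fc and 746 ± 356 in the IL-22-Fc libraries. A UMI of Il22 was seen in 24.5% ± 8.47 and 36.7% ± 10.3 of them, and in 21.6% and 22.2% after thinning. In B-like cells, which should lack it, the share was 0.0502% and 0.606%, at medians of 727 to 4560 UMIs against 934.5 to 6248 in ILC3-like cells.

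Class shares asked whether IL-22-Fc changed the cell types recovered. An exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333, so no share could pass it. Stem/TA-like cells made up 36.3% and 43.2% of the epithelial Fc libraries and 32.4% and 29.5% of the IL-22-Fc libraries (exact permutation p = 0.333). Enterocyte-like cells made up 17.2% and 14.9% against 16.7% and 22.2% (exact permutation p = 0.667), and tuft-like cells 3.11% and 2.21% against 1.56% and 1.84%. Clusters left unnamed held 9.54% and 12.5% of the Fc and 18.5% and 18.3% of the IL-22-Fc cells. A count model in edgeR called 0 of 10 epithelial classes, with 0 at an unadjusted p under 0.05. In the lamina propria it called 5 of 18. Stem/TA-like cells were 24.0% and 21.1% of the Fc libraries and 0.0455% and 0.0151% of the IL-22-Fc libraries (edgeR adjusted p = 8.98e-05). Dendritic-like cells were 0.19% and 0.93% against 8.03% and 4.15%, and fibroblast-like cells 0.0119% and 0.128% against 3.06% and 1.28% (edgeR adjusted p = 0.0466 and 0.0139). Neutrophil-like cells were 0.0475% and 0.0091% against 0.713% and 0.362% (edgeR adjusted p = 0.0365), and tuft-like cells 0.736% and 0.648% against 0.106% and 0 of 6622 cells (edgeR adjusted p = 0.0466). In the Fc libraries there were only 1 and 14 fibroblast-like and 4 and 1 neutrophil-like cells. With the replicate number as a block only the stem/TA-like and fibroblast-like shares passed (edgeR adjusted p = 0.00126 and 0.0481), and the dendritic-like, neutrophil-like and tuft-like shares did not (0.0848, 0.0649 and 0.0683). The lamina propria preparation was meant to leave epithelium behind, so epithelial cells in it reflect carry-over in the preparation as well as the tissue. Shares are of all called cells of a library, so this carry-over also shifts the shares of the other classes.

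**Figure D4:**
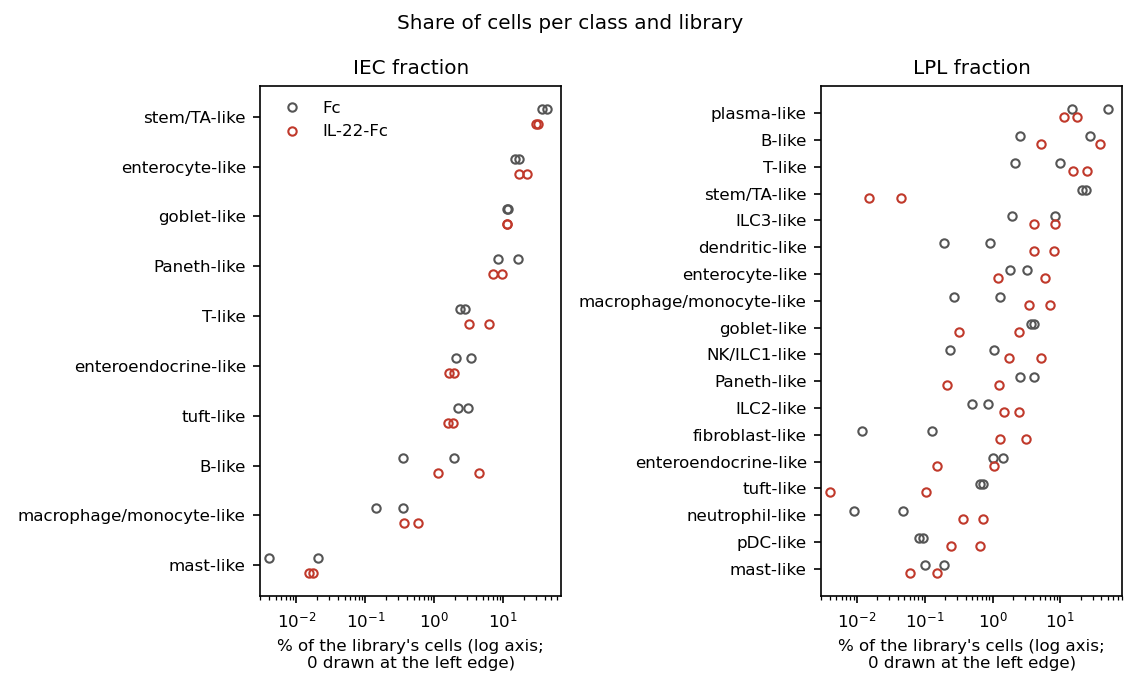
Percent of a library's cells in each class on a log axis, epithelial fraction left and lamina propria fraction right, 1 circle per library (grey Fc, red IL-22-Fc; 0 at the left edge). Lamina propria stem/TA-like cells lie at 24.0% and 21.1% in the Fc and below 0.05% in the IL-22-Fc libraries.

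Goblet-like cells carried over into the lamina propria preparation gave a second view of that class. Retnlb rose from 0.521 ± 0.0230 to 1492 ± 225 CPM (log2 change 11.43 ± 0.39, edgeR adjusted p = 1.16e-05), Fut2 from 0.529 ± 0.391 to 142 ± 24.9 CPM, Reg3g from 109.5 ± 48.1 to 15200 ± 207 CPM and Tac1 from 1.36 ± 0.0317 to 85.99 ± 28.6 CPM. Muc5ac, a mucin, rose from 1.38 ± 0.705 to 45.98 ± 29.9 CPM (log2 change 5.00 ± 0.62, edgeR adjusted p = 0.00958), Socs3 from 12.2 ± 0.262 to 81.7 ± 17.3 CPM and Nupr1 from 44.96 ± 1.69 to 417 ± 99.03 CPM. Slit2 fell from 78.5 ± 8.86 to 9.15 ± 3.45 CPM and Acot1 from 58.3 ± 10.7 to 2.83 ± 3.996 CPM. Of 18 IL-22/STAT3 list members, 12 rose (13 when adjusted over the list alone, median 1.85, camera adjusted p = 6.82e-09, and adjusted p = 0.569 with an estimated correlation), and of 21 cholesterol synthesis genes 8 rose (20 when adjusted over the list alone, median 1.03, camera adjusted p = 6.82e-09, and adjusted p = 0.569 with an estimated correlation). Of 12140 genes, edgeR called 592, 453 higher and 139 lower, and the groups did not overlap for 591 of them (61.3% of all tested genes, 33.3% by chance). The Fc cells lay in cluster 12 (350 and 405 cells) and nearly all IL-22-Fc cells in cluster 44 (156 and 21 cells), which is led by Retnlb. These goblet-like calls therefore compare different clusters. Without Fc replicate 1, Fc replicate 2, IL-22-Fc replicate 1 or IL-22-Fc replicate 2 the count was 102, 145, 3094 or 1853, and Acot1 did not pass without Fc replicate 1 (-3.53). Enterocyte-like cells of this preparation lay in cluster 20 in the Fc and mostly in clusters 27 and 54 in the IL-22-Fc libraries. Far fewer genes were called there at Leiden resolution 2 or without centring than with the main clustering. With the main clustering, the 2985 of 11559 genes that edgeR called there compare different clusters too. That count was 4733 without Fc replicate 2 and 1747 without IL-22-Fc replicate 1.

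Lamina propria lymphocytes were compared to ask whether IL-22-Fc changed immune cells, in which Il22ra1 was at 1 UMI in 1263 T-like Fc cells and at 0 in 2633 T-like IL-22-Fc cells. In T-like cells edgeR called 0 of 11523 genes, with 988 at an unadjusted p under 0.05, and DESeq2 called 69. With the replicate number as a block edgeR called 515, 212 higher and 303 lower. Il22 was at 11.8 ± 16.8 to 55.7 ± 17.96 CPM and Il17a, another cytokine of type 17 cells, at 80.7 ± 11.99 to 226 ± 128 CPM (edgeR adjusted p = 0.59 and 0.478). Ifng, the type 1 cytokine, was at 91.9 ± 65.7 to 105 ± 50.7 CPM, and Foxp3, the factor of regulatory T cells, at 4.82 ± 2.57 to 15.6 ± 17.8 CPM. None of 14 type 17 genes passed, over all genes or adjusted over the list alone, while the list stood higher than other genes (median 1.21, camera adjusted p = 3.58e-05, and adjusted p = 0.502 with an estimated correlation). The T-like cells of each library fell largely into clusters of their own, 47 in Fc replicate 1, 23 and 24 in Fc replicate 2, 9, 11 and 40 in IL-22-Fc replicate 1, and 19, 39 and 42 in IL-22-Fc replicate 2, and clusters 9 and 39 are led by Il17a. Without IL-22-Fc replicate 1 or 2 edgeR called 138 or 136 genes; without the latter Il22 and Il17a passed (log2 change 2.07 and 1.93), and without the former Foxp3 did (2.25), while Ifng turned to -0.37, as it did without Fc replicate 2 (-0.38).

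Innate lymphocytes held calls of their own. In ILC2-like cells (type 2 innate lymphocytes, 42 and 95 cells in the Fc and 161 and 97 in the IL-22-Fc libraries, all in cluster 26), edgeR called 104 of 5598 genes, 49 higher and 55 lower, with no overlap in any (47.9% of all tested genes, 33.3% by chance). Angpt1, a ligand of the receptor TIE2, rose from 20.7 ± 2.96 to 201 ± 43.4 CPM (log2 change 3.27 ± 0.53, edgeR adjusted p = 0.00658), and Tgm2, a transglutaminase, from 66.2 ± 77.5 to 600.5 ± 129 CPM. Med12l, of the Mediator complex, rose from 30.01 ± 10.2 to 279 ± 88.7 CPM. The cells compared differ in depth, with medians of 2013 and 1041 UMIs in the Fc and 5647 and 6977 in the IL-22-Fc libraries. Summed over the class, the Fc libraries held 94011 and 108617 UMIs and the IL-22-Fc libraries 903761 and 710572. The Fc levels of Angpt1 and Med12l thus rest on few UMIs. After subtraction of free RNA edgeR called 33 genes, 22 higher and 11 lower, and 55 with doublets kept or with the stricter mitochondrial maximum. In NK/ILC1-like cells edgeR called 34 of 6161 genes, 5 higher and 29 lower, with no overlap in any (48.5% of all tested genes, 33.3% by chance). Rab27b, which acts in granule release, rose from 99.4 ± 22.8 to 519 ± 41.3 CPM (log2 change 2.49 ± 0.40, edgeR adjusted p = 0.00434). Gzma, the protease granzyme A of cytotoxic granules, fell from 2496 ± 963 to 447 ± 112 CPM (log2 change -2.45 ± 0.38, edgeR adjusted p = 0.00342), and Prf1, which forms pores in target cells, from 549 ± 122 to 169.6 ± 0.745 CPM (log2 change -1.61 ± 0.27, edgeR adjusted p = 0.00668). These were 20 and 117 Fc and 337 and 116 IL-22-Fc cells, all in cluster 22 except for 94 cells of IL-22-Fc replicate 2 in cluster 50. The cluster 22 cells had medians of 1773.5 and 879 UMIs in the Fc and 4312 and 6625 in the IL-22-Fc libraries, and the cluster 50 cells 5612. The NK/ILC1-like sums held 35032 and 113366 UMIs in the Fc and 1528308 and 731727 in the IL-22-Fc libraries. The Fc level of Rab27b thus rests on few UMIs too. After subtraction of free RNA edgeR called 17 genes. Gzma and Prf1 did not pass without IL-22-Fc replicate 1 (log2 change -2.33 and -1.74) or 2 (-2.86 and -1.74). The NK/ILC1-like count was 84, 371, 14 and 18 without Fc replicate 1, Fc replicate 2, IL-22-Fc replicate 1 and IL-22-Fc replicate 2, and the ILC2-like count 166, 597 and 43 without Fc replicate 1, Fc replicate 2 and IL-22-Fc replicate 2.

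In 2 lymphocyte classes every called gene was lower. In B-like cells edgeR called 68 of 9615 genes, all lower, such as the epithelial adhesion genes Epcam (129.7 ± 34.5 to 10.6 ± 9.47 CPM) and Cldn7 (82.1 ± 1.58 to 7.41 ± 7.26 CPM). In ILC3-like cells it called 20 of 9303, all lower, such as the crypt genes Olfm4 (233 ± 53.5 to 11.9 ± 11.8 CPM) and Ang4 (79.5 ± 12.8 to 6.45 ± 0.745 CPM). The groups did not overlap for any of these 68 and 20 genes, against 43.3% and 47.7% of all tested genes and 33.3% by chance. Free RNA was estimated at up to 12.4% and 13.3% of B-like UMIs in the Fc libraries and 3.96% and 2.85% in the IL-22-Fc libraries. After its subtraction edgeR called 0 genes in either class, with 130 and 653 at an unadjusted p under 0.05, and with doublets kept it called 1 and 9. With a second profile of free RNA the counts were 2 and 0. B-like cells of each library formed their own clusters, 41 and 1 in the Fc and 32 and 2 in the IL-22-Fc libraries. The ILC3-like cells compared lay in clusters 15 and 6 in Fc replicate 1 (145 and 19 cells), Fc replicate 2 (382 and 542) and IL-22-Fc replicate 1 (97 and 453), but mostly in cluster 37 (255 cells) in IL-22-Fc replicate 2. In plasma-like and macrophage/monocyte-like cells edgeR called 0 of 12700 and 0 of 8168 genes, with 1628 and 989 at an unadjusted p under 0.05, and DESeq2 called 141 and 71. Most plasma-like cells of each library lay in a cluster of their own, 0 and 3 in the Fc libraries (4124 and 1582 cells) and 10 and 16 in the IL-22-Fc libraries (895 and 615). Resident macrophage genes stood higher than others (0 of 12 passed, 8 when adjusted over the list alone, median 0.94, camera adjusted p = 0.00348, and adjusted p = 0.715 with an estimated correlation), but not without Fc replicate 2 (camera adjusted p = 0.28). The macrophage/monocyte-like cells were a different mix of clusters 21 and 25 in each library, 7 and 16 cells and 24 and 116 cells in the Fc libraries and 326 and 144 and 111 and 114 in the IL-22-Fc libraries. The B-like count was 137, 499 and 281 without Fc replicate 1, Fc replicate 2 and IL-22-Fc replicate 1, and the ILC3-like count 121, 1356, 98 and 67, the macrophage count 59, 68, 30 and 45 and the plasma-like count 17, 1608, 237 and 77 without Fc replicate 1, Fc replicate 2, IL-22-Fc replicate 1 and IL-22-Fc replicate 2. Epcam and Cldn7 did not pass without Fc replicate 1 (-4.09 and -4.37) or 2 (-4.49 and -4.15), nor Olfm4 without them (-4.34 and -3.83).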

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

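Of the tests in this part, those of free RNA as the only source in B-, ILC3-, ILC2- and NK/ILC1-like cells, of Reg3b and Reg3g apart in Paneth-like cells, of the Reg3g change left after subtraction, of a second profile of free RNA, and of the counts left beside Reg3b and Reg3g in enterocyte-like cells were chosen after the result was seen. So was the rule that Reg3b and Reg3g both still pass after subtraction, used for goblet-like cells. The response to IL-22-Fc differed between enterocyte-like and stem/TA-like cells for 95 genes by a direct test of the difference between the 2 groups of cells. That count moved with the library left out and fell after subtraction of free RNA by the first profile. The test was not run within enterocyte-like clusters, whose mix differed between Fc and IL-22-Fc libraries. Barcodes with under 100 UMIs, which were not called as cells and entered only the subtraction of free RNA, also carried the signal. Reg3b made up 3.719% and 4.54% of their UMIs in the epithelial IL-22-Fc libraries, above 0.251% and 0.0714% in the Fc libraries. In the lamina propria it made up 1.379% and 0.4584%, above 0.0461% and 0.0166%. These barcodes hold a median of 1 UMI, so free RNA was also taken from the barcodes ranked 20000 to 60000 by UMIs, with medians of 67 to 294 UMIs. In lamina propria Fc replicate 2 and IL-22-Fc replicate 2 the ranked barcodes hold at most 93 and 82 UMIs. There they lie within the first set, so agreement of the profiles in lymphocytes is partly built in. Values by this second profile follow those by the first.

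Because of this free RNA, the rise of Reg3b and Reg3g outside enterocyte-like cells was weighed against it. Free RNA could carry at most 7.6% and 6.69% of their UMIs in stem/TA-like cells, which excludes it as the whole cause there, and after subtraction Reg3b stayed higher (log2 change from 7.04 ± 0.63 to 7.48 ± 0.66 and 7.56 ± 0.72). In goblet-like cells it could carry up to 34.4% and 30.3%, and 43.69% and 37.84% for Reg3b, which misses the bound of under 25% in each library that was set before. By a rule chosen after the result was seen, it is excluded there as the whole cause because both genes still passed after subtraction (Reg3b from 6.09 ± 0.61 to 6.73 ± 0.61 and 6.97 ± 0.71, Reg3g from 6.53 ± 0.43 to 6.83 ± 0.44 and 6.90 ± 0.39). Enterocyte markers stood at up to 3.66% of their enterocyte-like level in stem/TA-like cells, a smaller share than that of Reg3b and Reg3g. Enterocytes with full marker levels are therefore too few there to be the whole cause. The same markers named the classes, so enterocytes with low levels of them are not excluded. In Paneth-like cells the 2 genes together gave 49.9% and 70.3% and did not both pass after subtraction, which decides nothing. Reg3b alone gave 133% and 196%, so free RNA could be its whole source. Reg3g alone gave 19.8% and 28.9%, on both sides of the bound of 25%. Its log2 change was 5.21 ± 0.47 before and 5.25 ± 0.81 and 5.15 ± 0.71 after subtraction, where the call ended because the error grew. A change that stays this far above 0 excludes free RNA as the whole source of Reg3g, and a part stays open. In epithelial T-like cells free RNA could carry 146% by either profile, so it could be the whole source there; the share is an upper bound and can pass 100%.

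The fall of 12 called members of the fat absorption, sugar and PPARα lists in enterocyte-like cells (median log2 change -2.91) was weighed against 3 technical causes. In clusters 7 and 8 alone, the setting nearest 0, the median was -1.64 and 9 of the 12 passed. In clusters 10 and 15 alone it was -1.926 with 3 passing, and at equal weight of the 4 clusters -1.969 with 7 passing. The fall was thus smaller in each of these settings, so another mix of clusters may explain part of it. The 12 members were picked because they fell in the same cells, which favours medians below 0 here. Whether another mix explains the whole fall therefore stays open. After subtraction of free RNA the median was -2.92 and -2.94, so free RNA of these profiles, at its upper share, does not account for the fall of these members. The median of all tested genes was -0.0186, but scaling sets this near 0, so it decides nothing. The rise of Reg3b and Reg3g left a log2 ratio of -0.242 in the counts for other genes, before scaling. The median of the 12 members lies below that by more than their interquartile range of 1.817. These members were picked because they fell in TMM-scaled fits of the same data. That outcome was therefore fixed in advance and decides nothing about counts taken up by these 2 genes. A response to IL-22-Fc remains open, with only 2 libraries per group.

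The genes that fell in lamina propria lymphocytes were weighed against RNA from epithelial cells, which were more numerous in the Fc libraries. The bound set before the result was seen was a median difference within 0.5 between the fitted log2 change and the change that free RNA predicts: ILC3-like (0.4) and NK/ILC1-like cells (0.0196) met it, B-like (-0.912) and ILC2-like cells (-0.57) missed it, and none passed the opposite bound. The verdicts therefore rest on the test chosen after the result was seen, the percent of Fc UMIs of the falling genes that free RNA could carry. Counts of genes left after subtraction keep the markers that set the share of free RNA, whose loss is largely built in. The percent leaves these markers out. In ILC3-like cells it was 104% and 108%, and 0 of 20 genes passed after subtraction by either profile, so free RNA could be the source. In B-like cells it was 105% and 104%, but 0 and 1 of 68 genes passed after subtraction, so whether free RNA is the only source stays open. It was 3.33% and 2.74% in ILC2-like cells, where 10 and 13 of 55 genes still passed, and 15.2% and 16.8% in NK/ILC1-like cells, where 12 of 29 passed by either profile, so free RNA is not the only source there. It stays open for the 18 ILC2-like genes (by either profile) and the 8 and 10 NK/ILC1-like genes of which it could carry at least 50%.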

How the results depend on the processing

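Splits of the enterocyte-like class by cluster, the test of cluster 4, sums over all cells of a library and the second profile of free RNA were chosen after the data were seen; the other alternatives were planned. Of 4181 alternative values of single genes, 3772 kept direction and side of the threshold, 359 no longer passed, 36 newly passed, 12 of genes that had not passed changed sign, and 2 of a called gene reversed: Agr2 in enterocyte-like cells, at -9.76 and -1.38 after subtraction of free RNA by the first and the second profile. Of 297 alternative counts of genes, 144 stayed within 1.5 times and 153 did not. Except where fewer genes, cells or libraries explain it, the cause was not tested. The count by edgeR with RLE scaling stayed within 1.5 times in every class.

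With DESeq2 the counts of called genes that moved were enterocyte-like 810, Paneth-like 427, enteroendocrine-like 17, tuft-like 41, cluster 4 368, ILC3-like 58, NK/ILC1-like 21, lamina propria T-like 69, macrophage/monocyte-like 71, plasma-like 141 and the difference between enterocyte-like and stem/TA-like cells 181. With no low-count filter they were enterocyte-like 1078, stem/TA-like 2814, goblet-like 2801, Paneth-like 1666, epithelial T-like 18, tuft-like 480, enteroendocrine-like 57, B-like 433, ILC2-like 378, ILC3-like 345, NK/ILC1-like 74, lamina propria T-like 383, macrophage/monocyte-like 250, plasma-like 1018, lamina propria goblet-like 1827 and the difference 374. After subtraction of free RNA they were Paneth-like 0, epithelial T-like 2 (0 of the 9 called before), B-like 0, ILC2-like 33, ILC3-like 0, NK/ILC1-like 17, plasma-like 1 and the difference 44. With the second profile they were Paneth-like 0, epithelial T-like 0, B-like 2, ILC2-like 42, ILC3-like 0, NK/ILC1-like 18 and plasma-like 15.

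With doublets kept the counts were Paneth-like 235, enteroendocrine-like 90, B-like 1, ILC2-like 55, ILC3-like 9 and macrophage/monocyte-like 79. With the UMI minimum doubled they were B-like 29, ILC3-like 10 and macrophage/monocyte-like 37, and with the stricter mitochondrial maximum Paneth-like 59, ILC2-like 55 and lamina propria T-like 2. Thinned to the smallest total they were Paneth-like 53, cluster 4 354, B-like 25, ILC2-like 55, NK/ILC1-like 10 and lamina propria T-like 12. At Leiden resolution 2 they were B-like 191 and lamina propria enterocyte-like 295, and without centring Paneth-like 59, ILC3-like 36, lamina propria T-like 6, lamina propria enterocyte-like 330, lamina propria goblet-like 1089 and the difference 232. In clusters 10 and 15 alone, the enterocyte-like count was 185, and Slc5a1 and Slc2a5, which had not passed, stood at 0.27 and 0.33.

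The libraries share only a replicate number, and the deviations from the group mean of libraries with equal numbers correlated between -0.278 and 0.236 over the classes. With this number as a block the counts that moved were stem/TA-like 2478, Paneth-like 216, epithelial T-like 15, tuft-like 403, enteroendocrine-like 0, B-like 261, ILC2-like 324, ILC3-like 7, NK/ILC1-like 63, lamina propria T-like 515, macrophage/monocyte-like 5, plasma-like 22 and lamina propria goblet-like 2347. The difference between classes already holds a term per library and was not run with this block. The count of lamina propria classes with a changed share was 0 by permutation, 5 by edgeR and 2 by edgeR with the block.

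With each library left out in turn the counts ran from 128 to 3064 in enterocyte-like, 608 to 5792 in stem/TA-like, 118 to 5350 in goblet-like, 71 to 5252 in Paneth-like, 13 to 238 in epithelial T-like, 49 to 563 in tuft-like, 4 to 630 in enteroendocrine-like cells and 341 to 2033 in cluster 4. In the lamina propria they ran from 58 to 499 in B-like, 43 to 597 in ILC2-like, 67 to 1356 in ILC3-like, 14 to 371 in NK/ILC1-like, 0 to 138 in T-like, 30 to 68 in macrophage/monocyte-like, 17 to 1608 in plasma-like, 1747 to 4733 in enterocyte-like and 102 to 3094 in goblet-like cells, and for the difference from 0 to 1209. A library left alone in its group is assumed to vary like the other group. In sums over all cells of a library edgeR called 677 genes in the epithelial fraction, 1664 by DESeq2, 1977 with no filter, 1575 with the block, 3171 without Fc replicate 2 and 365 without IL-22-Fc replicate 2. In the lamina propria it called 0, with 5866 at an unadjusted p under 0.05, 3436 by DESeq2, 2487 with no filter, 1995 with the block, 417 without Fc replicate 2 and 4925 without IL-22-Fc replicate 1.

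Over all classes 181 tests of gene lists passed with camera at the preset correlation, 0 with an estimated correlation and 21 with fry. Of 3115 alternative values of single lists, 2339 kept direction and side of the threshold and 441 no longer passed. Another 148 newly passed, 185 that had not passed changed direction, and 2 reversed. Of 119 alternative counts of lists per class, 76 stayed within 1.5 times and 43 did not. In enteroendocrine-like cells the dissociation list reversed without Fc replicate 1 (camera adjusted p = 0.114), and with each library left out ran from 1.65e-08 to 0.653. The goblet and mucus list reversed without IL-22-Fc replicate 2 (camera adjusted p = 0.653), and ran from 5.94e-16 to 0.653. Depth limits shares of cells with a UMI: thinned to 1000 UMIs per cell, the share of enterocyte-like Fc cells with Il22ra1 was 1.34% in place of 8.15%.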

Other observations

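The test of overlap in this part was set before its result was seen. Retnlb and Nupr1 rose in goblet-like cells of both fractions, and so did Zbp1, a sensor of nucleic acids. Zbp1 rose from 6.68 ± 0.716 to 41.2 ± 2.39 CPM in the lamina propria (log2 change 2.58 ± 0.26, edgeR adjusted p = 0.00309) and from 13.7 ± 6.71 to 49.6 ± 4.31 CPM in the epithelial fraction (log2 change 1.80 ± 0.28, edgeR adjusted p = 0.0216), where it did not pass without IL-22-Fc replicate 1 (1.90). Pdk4, a kinase that limits the use of glucose, fell in the lamina propria goblet-like cells from 42.4 ± 2.33 to 10.7 ± 3.89 CPM, but did not pass without Fc replicate 2 (-2.09).

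It was asked whether the goblet-like calls of the 2 fractions overlap as independent lists would. Among 11570 genes tested in both, 238 were higher in both (22.5 by chance) and 99 lower in both (5.61 by chance), 0 went opposite ways, and the shared calls were 12 times the chance number. Lists drawn independently and evenly from these genes are therefore excluded. The chance number takes every gene as equally likely to be called, so it does not allow for genes measured well in both fractions. The lamina propria calls also compare different clusters. Libraries of the 2 fractions could come from the same mice, so this is no replication in other animals.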
